A study of Mus musculus with 15 samples.

How the data were processed

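Gene expression was measured on 15 one-colour Affymetrix arrays, 3 for each of 5 groups: pre-uDC sorted from bone marrow of mice labelled as 10 to 14 days old, and CD103+CD11b- and CD103+CD11b+ cells sorted from 5-day cultures, with and without RA, of pre-uDC labelled as from adult males. Per the labels' protocols, total RNA was amplified with the Ambion WT Expression kit and labelled with biotin for Affymetrix GeneChip WT arrays. The deposited values are intensity values on a linear scale from 22.9 to 21655, normalized between arrays by the authors, and the submitters' processing notes name Partek and RMA without versions or settings. The deposited table holds 16858 probe sets, and how they were chosen from the array is not stated. A second deposited table held the same 15 columns with 100% of values identical, beside 18 columns from another series that were not used.

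The log2 of the deposited intensity was taken before all tests. The platform annotation gave 1 gene symbol to 13582 probe sets, several to 899 and none to 2377, and probe sets with several or none were left out. Of the symbols, 13553 matched the reference through their gene identifier. For the 694 genes with several probe sets, the one with the highest mean over all arrays was used, which left 12387 genes. Probe sets of a gene were called in opposite directions for 2 genes in the RA effect in CD11b- cells, 2 in the subset comparison with RA, 18 in the precursor comparison and 0 in the others. No filter on low values was applied, and a dim probe set can hide or shrink a change. Of all probe sets, 686 reached an intensity of 120 on no array.

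All 15 arrays were fitted together with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings), so that groups of 3 share 1 estimate of the spread. The comparisons were the RA effect in each subset, CD11b+ minus CD11b- cells without and with RA, the difference of the RA effect between the subsets, and the mean of the cultured groups minus pre-uDC. P-values were two-sided and adjusted by Benjamini-Hochberg within each comparison, and genes with an adjusted p under 0.05 were called. Sets of genes were tested with camera at a preset correlation of 0.01 over 26 lists and 6 comparisons, adjusted over all of these tests together. Of 51 list calls, that of the plasmacytoid markers in the precursor comparison was the only one kept with a correlation estimated from the residuals (adjusted p = 0.00608). Lists were counted over all genes tested and also adjusted over the list alone. Several lists share genes, and monocyte, progenitor and T and NK lists hold genes that DC also express. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

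The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule named, for each comparison of 3 against 3 arrays, the 10 genes with the largest called increase and the 10 with the largest decrease whose groups did not overlap in any array, 8 and 8 in the precursor comparison and 5 and 5 for the difference of the RA effect, leaving out predicted genes and receptor segments. It also named up to 4 members of each list with the lowest adjusted p, and 20 genes of DC identity, RA response and gut homing whatever their value. The fit was tested on simulated data for the RA effect in CD11b- cells over 12387 genes: 99 of 100 genes changed by a log2 of 1 and 100 of 100 changed by a log2 of 2 were recovered, with 9 false calls and 1 call in a comparison left unchanged. A simulated list left unchanged had an unadjusted camera value of 0.0108, under 0.05.

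Within groups, arrays correlated at r = 0.979 to 0.992 across genes. Whether arrays with the same replicate number deviate together from their group means was checked. The correlations were 0.438 to 0.677 between the subsets without RA, 0.250 to 0.590 between the subsets with RA and 0.197 to 0.406 between CD11b- cells with and without RA, so these numbers pair the samples, as read from the data and not from the labels. For CD11b+ cells with and without RA they were 0.041 to 0.326, and with pre-uDC -0.13 to 0.10, so those were not taken as pairs. The alternatives tried were quantile normalization, centring each array on its median, leaving out the genes below the median level, testing every probe set, a trended robust eBayes, fitting only the groups compared, array weights, a replicate block and leaving out each array in turn. A replicate block among the cultured arrays alone (the cultured-array block) was added after seeing the data. Lists were tested under the scalings, the gene filter, the replicate blocks and the left-out arrays only. The second table gave identical values and so no further alternative. Scan dates are not given, so batches could not be tested.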

Results

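Gene expression was measured on 15 mouse Affymetrix arrays in 5 groups of 3 samples each. One group was the sorted bone marrow precursor called pre-uDC, a pre-mucosal dendritic cell (DC), labelled as from mice 10 to 14 days old. The other groups were conventional DC sorted after 5 days of culture, with the growth factors Flt3L and GM-CSF, of pre-uDC labelled as from bone marrow of adult males. These ages are as the labels give them, and the unit of the first could not be checked. The cultures were grown with or without retinoic acid (RA), the vitamin A metabolite that acts through nuclear receptors. From each culture condition, CD103+CD11b- cells and CD103+CD11b+ cells were profiled, below called CD11b- and CD11b+ cells. Median array intensity lay between 274 and 329. The number of arrays, 3 per group, limited the precision. The labels do not say whether replicates are separate animals or cultures, so p-values measure the spread between these samples, which may be technical. Values after gene names are log2 fold changes ± SE from limma, with n = 3 arrays per group, unless a fold or an intensity is named. Where the lower level compared has a mean intensity of at most 120, near background, a called change is only a bound, written ≥, ≤ or at least. Lists give measured members and their median log2 fold change. Ranges of p over alternatives leave out the estimated correlation, which is given apart.

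The effect of RA in CD11b- cells addressed how RA shapes the subset that resembles type 1 conventional DC (cDC1). With RA, cell cycle genes were higher and genes of DC maturation were lower. Of 32 cell cycle list members, 31 were higher and 0 lower (32 and 0 adjusted over the list alone), with a median log2 of 1.40. The cell cycle list gave camera adjusted p = 4.31e-13 (7.86e-15 to 1.31e-10 over alternatives), adjusted p = 0.365 with an estimated correlation. Ccnb2, a mitotic cyclin (2.02 ± 0.16), Foxm1, a transcription factor of mitosis (1.61 ± 0.13), and the kinase Plk1 (1.78 ± 0.15) rose. Of 23 costimulation and maturation list members, 2 were higher and 21 lower (2 and 21 adjusted over the list alone), with a median log2 of -1.78. The costimulation and maturation list gave camera adjusted p = 6.43e-12 (4.32e-14 to 5.02e-09 over alternatives), adjusted p = 0.365 with an estimated correlation. The costimulatory receptor Cd40 fell 5.66-fold (-2.50 ± 0.12), Cd86 3.55-fold (-1.83 ± 0.12) and the NF-kappaB subunit Relb 5.12-fold (-2.36 ± 0.15). The chemokine Ccl17 rose 7.02-fold (2.81 ± 0.16).

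Markers of cDC1 were higher with RA in CD11b- cells. Of 21 cDC1 markers list members, 13 were higher and 2 lower (13 and 3 adjusted over the list alone), with a median log2 of 1.06. The cDC1 markers list gave camera adjusted p = 0.00217 (0.000473 to 0.0169 over alternatives), adjusted p = 0.416 with an estimated correlation. Tlr3, a receptor for double-stranded RNA, rose 16.1-fold from a mean intensity of 235 to 3766 (4.00 ± 0.15, adjusted p = 3.44e-13). The dead-cell receptor Clec9a rose 3.20-fold (1.68 ± 0.13) and the chemokine receptor Xcr1 3.85-fold (1.95 ± 0.25). The cDC2 markers list was not called as a set (camera adjusted p = 0.301). Of its members, Irf4, a transcription factor of type 2 conventional DC (cDC2), fell 6.99-fold from 1548 to 221 (-2.81 ± 0.20, adjusted p = 1.52e-09). The lectin receptor Clec12a rose (1.99 ± 0.15) and S100a4 fell (≤ -4.53 ± 0.19).

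Of the known RA targets, Rarb (≥ 1.48 ± 0.11), Hic1 (2.76 ± 0.20), Asb2 (1.99 ± 0.15) and Cyp26b1 (1.39 ± 0.13), which degrades RA, rose in CD11b- cells. Of 15 retinoic acid receptors and responsive genes list members, 4 were higher and 4 lower (4 and 4 adjusted over the list alone), with a median log2 of -0.07. The list gave camera adjusted p = 0.890, not called. The set test pointed up, with a mean of 0.25. Aldh1a2, the enzyme that makes RA from retinal, rose 4.53-fold (2.18 ± 0.16). Dhrs9 (1.98 ± 0.13) and Rdh11 (1.21 ± 0.13) rose, while Rbp4 (≤ -2.62 ± 0.29) fell. Of 8 retinoid synthesis list members, 5 were higher and 1 lower (5 and 1 adjusted over the list alone), with a median log2 of 0.40. The list gave camera adjusted p = 0.103, not called. Of 8 gut homing and mucosal receptors list members, 2 were higher and 4 lower (2 and 4 adjusted over the list alone), with a median log2 of -0.20. The list gave camera adjusted p = 0.525, not called. Itga4 (-1.39) and Gpr183 (-0.89) fell. Of 17 glycolysis and hypoxia list members, 15 were higher and 0 lower (15 and 0 adjusted over the list alone), with a median log2 of 1.13. The glycolysis and hypoxia list gave camera adjusted p = 1.57e-05 (3.13e-07 to 7.24e-05 over alternatives), adjusted p = 0.365 with an estimated correlation. Egln3 (2.77 ± 0.25) and Pgam1 (1.18 ± 0.11) rose. Of 18 type I interferon response list members, 0 were higher and 8 lower (0 and 8 adjusted over the list alone), with a median log2 of -0.31. The type I interferon response list gave camera adjusted p = 0.0106 (0.00354 to 0.155 over alternatives), adjusted p = 0.416 with an estimated correlation. Usp18 (-1.71 ± 0.12) and Oas3 (-1.77 ± 0.17) fell. For type I interferon response, the call ended without the genes below the median level (0.155).

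The largest increases with RA in CD11b- cells were Ifitm6 (≥ 5.67 ± 0.18), Pilra (≥ 5.60 ± 0.16), Ppef1 (≥ 5.22 ± 0.13) and Arhgap6 (≥ 4.85 ± 0.11) among genes whose groups did not overlap. Mmp9, Qpct, Cd34, Tpcn1, Treml4 and Pltp followed, at 4.69 to 4.18. Ifitm6 rose at least 50.8-fold (adjusted p = 2.08e-14). The largest decreases in CD11b- cells were Il12rb2 (≤ -5.34 ± 0.26), Cd207 (≤ -5.24 ± 0.18), S100a6 (≤ -4.61 ± 0.25) and Adgrg6 (-4.61 ± 0.17). S100a4, Icos, Gramd3, H2-Eb2, Cd3g and Prnp followed, at -4.53 to -3.86. Of these 20, 16 rest on a level near background, their order uncertain. Il12rb2, a subunit of the interleukin-12 receptor, fell at least 40.6-fold (adjusted p = 5.60e-12). Cd3g belongs to the T cell receptor complex and Cd34 marks progenitors. The T and NK cell markers (0.379), myeloid progenitor genes (0.763), neutrophil markers (0.714) and monocyte and macrophage markers (0.714) lists were not called, by their camera adjusted p.

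Itgam, which encodes the CD11b used for the sort, rose at least 5.45-fold in these CD11b- cells (≥ 2.45 ± 0.17). Itgae (1.04 ± 0.19), Itgb7 (0.68 ± 0.17) and Trem1 (≥ 0.44 ± 0.12, 58.3 to 79.0, both near background) rose. Sirpa (-0.69 ± 0.15) and Csf2rb (-0.82 ± 0.13) fell. Irf8 (0.21 ± 0.11), Rara (-0.19 ± 0.15), Cd101 (0.10 ± 0.13) and Flt3 (-0.09 ± 0.11) were not called. Batf3 (-0.49 ± 0.22, adjusted p = 0.0689, 0.00286 to 0.423 over alternatives) was called with arrays centred on their median (0.0214), with array weights (0.00330) and without replicate 3 of CD11b- cells with RA (0.00286). Cd8a (-0.07 ± 0.13, adjusted p = 0.727, 0.354 to 0.957 over alternatives) changed sign without replicate 2 of CD11b- cells without RA or replicate 3 of CD11b- cells with RA (0.0141 to 0.0318). Dhrs3 (0.27 ± 0.13, adjusted p = 0.0867, 0.0304 to 0.315 over alternatives) was called without replicate 2 of CD11b- cells without RA (0.0304). Ccr9 (≤ -0.48 ± 0.20, adjusted p = 0.0482, 0.00460 to 0.231 over alternatives) was not called with quantile normalization (0.0566), with every probe set tested (0.0638), with trended robust eBayes (0.0505) and without replicate 1 or 3 of CD11b- cells without RA or replicate 2 or 3 of CD11b- cells with RA (0.0518 to 0.231). Zbtb46 (-0.32 ± 0.13, adjusted p = 0.0536, 0.00344 to 0.171 over alternatives) was called with quantile normalization (0.0168), with arrays centred on their median (0.00987), with only the compared groups fitted (0.0312), with array weights (0.00344) and without replicate 3 of CD11b- cells with RA (0.0319).

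In this comparison 5957 of 12387 genes were called at an adjusted p under 0.05 by limma, 3523 higher and 2434 lower, and 1601 changed at least 2-fold. Over all genes, the arrays with and without RA did not overlap in 7067 (57.1%), where chance gives 10%. With each array centred on its median the calls split into 2783 higher and 3146 lower genes, in place of 3523 and 2434.

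**Figure D1:**
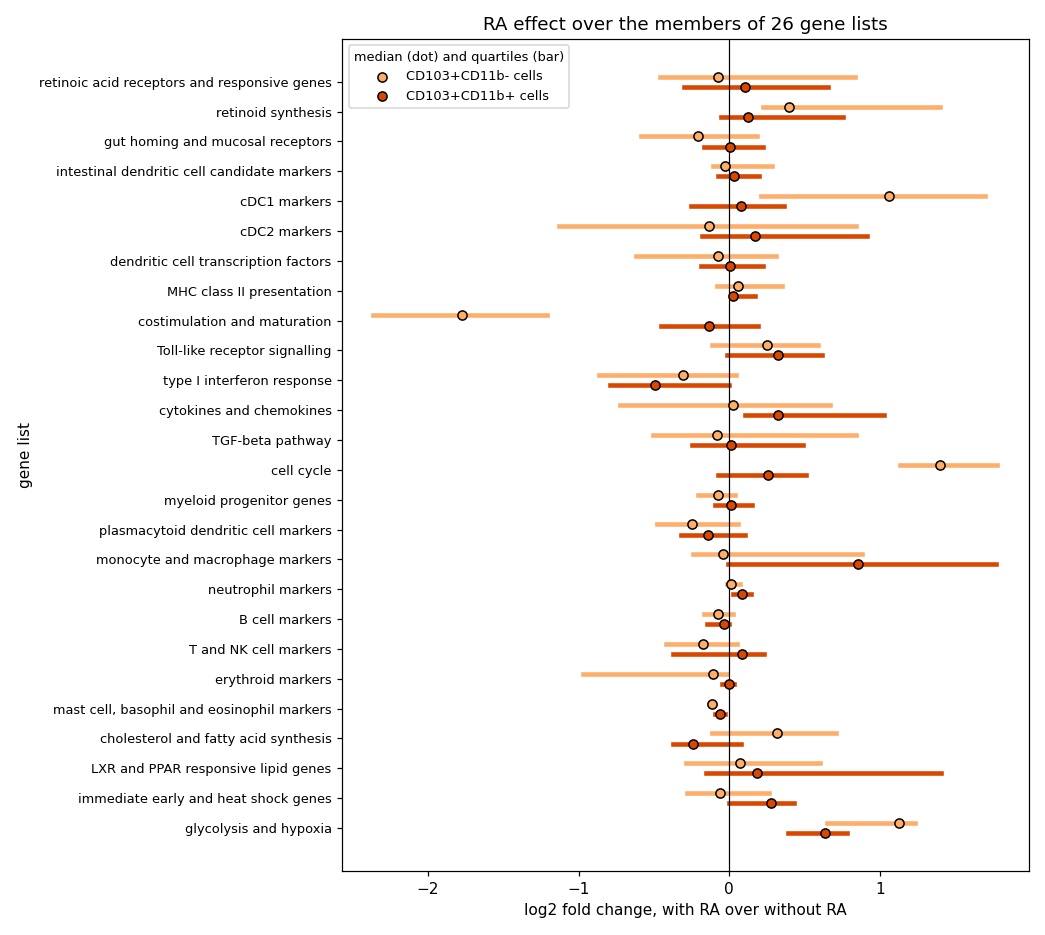
RA effect over the members of 26 fixed gene lists. The x axis gives the log2 fold change with RA over without RA, dots are medians over the measured members, bars span their quartiles, and colour gives the subset. The cell cycle median is 1.40 in CD11b- and 0.26 in CD11b+ cells.

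The effect of RA in CD11b+ cells addressed the subset that resembles cDC2. With RA, Aldh1a2 rose at least 17.2-fold, from a mean intensity of 97.0 to 1670 (≥ 4.11 ± 0.16, adjusted p = 8.94e-13). Among surface proteins listed as candidate markers of intestinal DC, Trem1 rose at least 3.68-fold (≥ 1.88 ± 0.12), Siglecf 3.75-fold (1.91 ± 0.12) and Cd101 at least 2.79-fold (≥ 1.48 ± 0.13). Ido1, which degrades tryptophan, fell 3.31-fold (-1.72 ± 0.15). Of 13 intestinal dendritic cell candidate markers list members, 3 were higher and 2 lower (3 and 3 adjusted over the list alone), with a median log2 of 0.03. The intestinal dendritic cell candidate markers list gave camera adjusted p = 0.538, not called.

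Monocyte and macrophage markers were higher with RA in CD11b+ cells. Of 16 monocyte and macrophage markers list members, 9 were higher and 2 lower (10 and 3 adjusted over the list alone), with a median log2 of 0.85. The monocyte and macrophage markers list gave camera adjusted p = 3.11e-05 (8.92e-07 to 0.00391 over alternatives), adjusted p = 0.257 with an estimated correlation. The efferocytosis receptor Mertk (≥ 2.51 ± 0.13), Cd68 (1.75 ± 0.15) and the complement component C1qb (2.63 ± 0.26) rose. Of 26 cytokines and chemokines list members, 9 were higher and 2 lower (9 and 2 adjusted over the list alone), with a median log2 of 0.32. The cytokines and chemokines list gave camera adjusted p = 0.000686 (3.58e-05 to 0.00968 over alternatives), adjusted p = 0.369 with an estimated correlation. Ccl6 (2.89 ± 0.18), Ccl17 (1.45 ± 0.16) and Il18 (≥ 1.13 ± 0.16) rose. Of 13 LXR and PPAR responsive lipid genes list members, 5 were higher and 2 lower (5 and 2 adjusted over the list alone), with a median log2 of 0.18. The LXR and PPAR responsive lipid genes list gave camera adjusted p = 0.00217 (0.000699 to 0.492 over alternatives), adjusted p = 0.250 with an estimated correlation. Lipoprotein lipase Lpl rose at least 10.4-fold (≥ 3.38 ± 0.11). For LXR and PPAR responsive lipid genes, the call ended without the genes below the median level (0.492). Of 17 glycolysis and hypoxia list members, 12 were higher and 0 lower (14 and 0 adjusted over the list alone), with a median log2 of 0.64. The glycolysis and hypoxia list gave camera adjusted p = 1.37e-07 (1.94e-08 to 8.33e-06 over alternatives), adjusted p = 0.309 with an estimated correlation. Egln3 (2.96 ± 0.25) and Ero1a (1.83 ± 0.21) rose.

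Interferon-response genes were lower with RA in CD11b+ cells. Of 18 type I interferon response list members, 2 were higher and 10 lower (2 and 10 adjusted over the list alone), with a median log2 of -0.49. The type I interferon response list gave camera adjusted p = 0.00286 (0.000240 to 0.175 over alternatives), adjusted p = 0.369 with an estimated correlation. Rtp4 (≤ -1.43 ± 0.14), Irf7 (-1.19 ± 0.13) and Oas2 (-1.15 ± 0.18) fell. For type I interferon response, the call ended without the genes below the median level (0.175). Of 13 Toll-like receptor signalling list members, 5 were higher and 1 lower (6 and 2 adjusted over the list alone), with a median log2 of 0.33. The Toll-like receptor signalling list gave camera adjusted p = 0.0269 (0.0108 to 0.420 over alternatives), adjusted p = 0.369 with an estimated correlation. Unc93b1 (1.52 ± 0.12) and Tlr1 (≥ 1.32 ± 0.13) rose. For Toll-like receptor signalling, the call ended without the genes below the median level (0.420) and without replicate 2 of CD11b+ cells without RA or replicate 3 of CD11b+ cells with RA (0.0563 to 0.0616). Of 32 cell cycle list members, 8 were higher and 0 lower (8 and 1 adjusted over the list alone), with a median log2 of 0.26. The cell cycle list gave camera adjusted p = 0.0350 (0.000452 to 0.256 over alternatives), adjusted p = 0.766 with an estimated correlation. For cell cycle, the call ended with the cultured-array block (0.0673) and without replicate 1 or 2 of CD11b+ cells without RA or replicate 1 or 2 of CD11b+ cells with RA (0.112 to 0.256). Mki67 rose 1.73-fold (0.79 ± 0.16). Of 20 cDC2 markers list members, 7 were higher and 5 lower (9 and 5 adjusted over the list alone), with a median log2 of 0.17. The cDC2 markers list gave camera adjusted p = 0.188, not called. The lectins Mgl2 (2.84 ± 0.22) and Cd209a (3.55 ± 0.30) rose.

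The largest increases with RA in CD11b+ cells were C3ar1 (≥ 4.55 ± 0.19), Pltp (4.37 ± 0.14), Klk1b11 (4.13 ± 0.14) and Aldh1a2 (≥ 4.11 ± 0.16) among genes whose groups did not overlap. Tbxas1, Gda, Cd209a, Tpcn1, Lpl and Fcgr3 followed, at 4.07 to 3.30. The largest decreases in CD11b+ cells were Cd3g (≤ -5.98 ± 0.23), Icos (-4.00 ± 0.14), Gramd3 (-3.60 ± 0.16) and Hpgds (≤ -3.42 ± 0.34). Ebf1, S100a4, Pgf, Calcb, Mest and Grap2 followed, at -2.88 to -2.66. Of these 20, 11 rest on a level near background, their order uncertain. Cd3g fell at least 63.3-fold (adjusted p = 8.94e-13) and the T cell costimulator Icos 16-fold. The T and NK cell markers list was not called (camera adjusted p = 0.649), nor was the B cell markers list (0.257), although Ebf1, a transcription factor of B cells, fell at least 7.34-fold. Of 15 retinoic acid receptors and responsive genes list members, 5 were higher and 3 lower (5 and 3 adjusted over the list alone), with a median log2 of 0.11. The list gave camera adjusted p = 0.248, not called. Hic1 (1.83 ± 0.20) and Asb2 (1.13 ± 0.15) rose. Itgae (0.93 ± 0.19), Itgam (2.03 ± 0.17), Sirpa (0.86 ± 0.15), Rarb (≥ 0.45 ± 0.11) and Dhrs3 (0.86 ± 0.13) rose. Itgb7 (0.70 ± 0.17) rose. Cd8a (-0.87 ± 0.13), Ccr9 (≤ -1.11 ± 0.20, 105 to 48.5, both near background) and Flt3 (-0.76 ± 0.11) fell. Irf8 (-0.19 ± 0.11), Csf2rb (-0.07 ± 0.13) and Xcr1 (0.16 ± 0.25) were not called. Irf4 (-0.01 ± 0.20, adjusted p = 0.983, 0.856 to 0.994 over alternatives) changed sign with quantile normalization (0.0212), with array weights (0.0153) and without replicate 1 of CD11b+ cells without RA or replicate 2 of CD11b+ cells with RA (0.0240 to 0.0955). Batf3 (0.08 ± 0.22, adjusted p = 0.883, 0.570 to 0.949 over alternatives) changed sign without replicate 3 of CD11b+ cells without RA or replicate 1 of CD11b+ cells with RA (-0.0683 to -0.0446). Rara (-0.29 ± 0.15, adjusted p = 0.206, 0.0167 to 0.628 over alternatives) was called with the cultured-array block (0.0167) and with array weights (0.0448). Clec9a (≥ 0.36 ± 0.13, adjusted p = 0.0491, 0.0240 to 0.117 over alternatives) was not called with quantile normalization (0.0816), with every probe set tested (0.0618), with trended robust eBayes (0.0529) and without replicate 1, 2 or 3 of CD11b+ cells without RA or replicate 1, 2 or 3 of CD11b+ cells with RA (0.0840 to 0.117). Zbtb46 (0.08 ± 0.13, adjusted p = 0.785, 0.373 to 0.906 over alternatives) changed sign without replicate 3 of CD11b+ cells without RA or replicate 3 of CD11b+ cells with RA (-0.0511 to -0.0339).

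In this comparison 2730 of 12387 genes were called at an adjusted p under 0.05 by limma, 1352 higher and 1378 lower, and 569 changed at least 2-fold. Over all genes, the arrays with and without RA did not overlap in 4177 (33.7%), where chance gives 10%. Of the genes called in both subsets, 1008 were higher and 972 lower with RA in both, where independent lists would share 384.5 and 270.8, and 147 moved in opposite directions. The RA effects of the subsets correlated across genes at r = 0.624. Arrays with the same number deviate together between the subsets, which can raise this overlap and r. Between differently numbered arrays r was 0.368 to 0.678, and genes are not independent replicates.

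**Figure D2:**
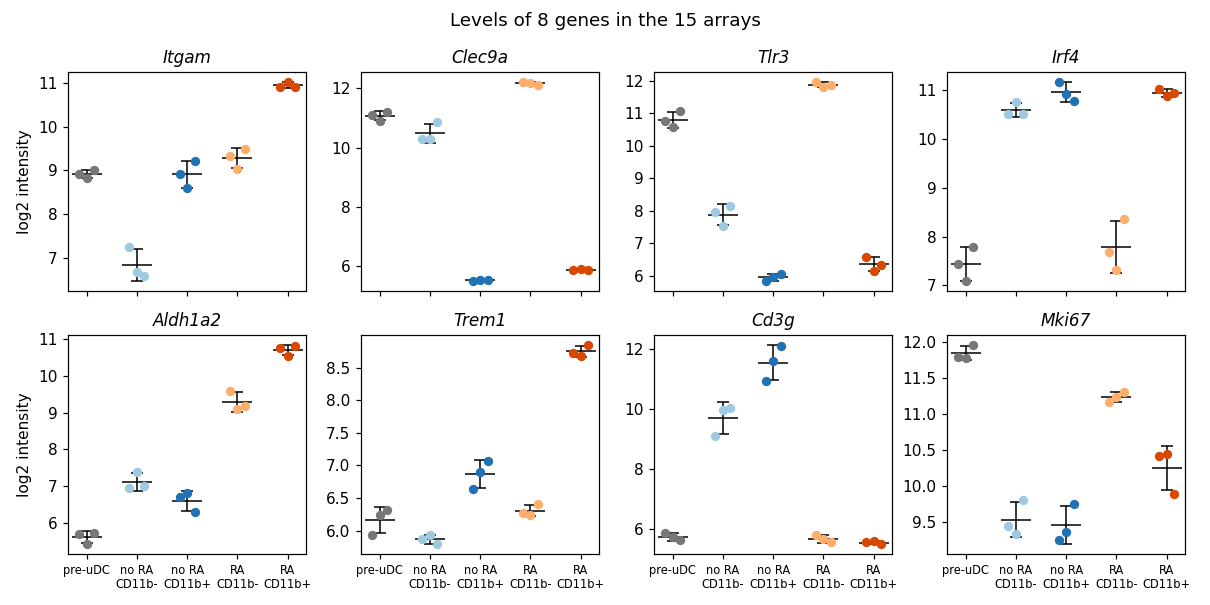
Levels of 8 genes in the 15 arrays. Each panel gives log2 intensity on the y axis for pre-uDC and the 4 cultured groups, dots are arrays, bars are the mean ± SD, and the y axes start above 0. Mean Aldh1a2 intensity is 1670 in CD11b+ cells with RA and 97.0 without.

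The subsets cultured without RA were compared to find which genes separated CD11b+ from CD11b- cells. Itgam, the sorting marker, differed by construction (≥ 2.07 ± 0.17), so it is no finding. CD11b+ cells had lower levels of cDC1 markers and higher levels of cDC2 markers. Of 21 cDC1 markers list members, 1 was higher and 16 lower (1 and 16 adjusted over the list alone), with a median log2 of -1.88. The cDC1 markers list gave camera adjusted p = 2.87e-20 (5.76e-23 to 2.09e-16 over alternatives), adjusted p = 0.107 with an estimated correlation. Clec9a was at least 31.2-fold lower (≤ -4.96 ± 0.13, adjusted p = 4.39e-15), Xcr1 at least 16.7-fold (≤ -4.06 ± 0.25) and Rab7b 15.7-fold (-3.97 ± 0.18). Of 20 cDC2 markers list members, 7 were higher and 2 lower (9 and 2 adjusted over the list alone), with a median log2 of 0.40. The cDC2 markers list gave camera adjusted p = 1.42e-06 (6.49e-08 to 0.000947 over alternatives), adjusted p = 0.250 with an estimated correlation. The lectin receptors Clec4a4 (≥ 3.64 ± 0.14) and Clec4a1 (3.16 ± 0.23), and Sirpa (2.22 ± 0.15), were higher.

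Other lists also separated the subsets without RA. Of 18 type I interferon response list members, 5 were higher and 1 lower (7 and 1 adjusted over the list alone), with a median log2 of 0.20. The type I interferon response list gave camera adjusted p = 0.00259 (8.31e-05 to 0.914 over alternatives), adjusted p = 0.369 with an estimated correlation. Rtp4 (≥ 1.97 ± 0.14) and Cxcl10 (1.20 ± 0.16) were higher. For type I interferon response, the call ended without the genes below the median level (0.914, direction turned). Of 13 Toll-like receptor signalling list members, 2 were higher and 6 lower (2 and 6 adjusted over the list alone), with a median log2 of -0.24. The Toll-like receptor signalling list gave camera adjusted p = 0.0269 (0.0119 to 0.113 over alternatives), adjusted p = 0.369 with an estimated correlation. Tlr12 (≤ -2.21 ± 0.17) and Tlr3 (≤ -1.93 ± 0.15) were lower. For Toll-like receptor signalling, the call ended without the genes below the median level (0.113), with the cultured-array block (0.0567) and without replicate 2 of CD11b+ cells without RA (0.0723). Of 18 cholesterol and fatty acid synthesis list members, 0 were higher and 5 lower (0 and 6 adjusted over the list alone), with a median log2 of -0.28. The cholesterol and fatty acid synthesis list gave camera adjusted p = 8.54e-05 (1.01e-05 to 0.000767 over alternatives), adjusted p = 0.369 with an estimated correlation. Lss (-0.58 ± 0.11) was lower. Of 13 LXR and PPAR responsive lipid genes list members, 1 was higher and 5 lower (2 and 5 adjusted over the list alone), with a median log2 of -0.19. The LXR and PPAR responsive lipid genes list gave camera adjusted p = 0.00217 (0.00101 to 0.0157 over alternatives), adjusted p = 0.250 with an estimated correlation. Cd36 (-2.51 ± 0.19) and Lpl (≤ -1.23 ± 0.11) were lower. Of 15 myeloid progenitor genes list members, 4 were higher and 0 lower (4 and 0 adjusted over the list alone), with a median log2 of 0.12. The myeloid progenitor genes list gave camera adjusted p = 0.0209 (0.00780 to 0.0636 over alternatives), adjusted p = 0.345 with an estimated correlation. Kit (1.79 ± 0.14) and Meis1 (≥ 1.19 ± 0.15) were higher. For myeloid progenitor genes, the call ended without the genes below the median level (0.0636) and with the cultured-array block (0.0517). Of 6 T and NK cell markers list members, 3 were higher and 0 lower (3 and 0 adjusted over the list alone), with a median log2 of 0.38. The T and NK cell markers list gave camera adjusted p = 0.0177 (0.00819 to 0.0559 over alternatives), adjusted p = 0.250 with an estimated correlation. Klrd1 (≥ 2.59 ± 0.27) and Cd3g (1.84 ± 0.23) were higher. For T and NK cell markers, the call ended with the cultured-array block (0.0559).

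The genes most above CD11b- cells were Pilra (≥ 4.10 ± 0.16), Clec4a4 (≥ 3.64 ± 0.14), Adgre1 (≥ 3.54 ± 0.17) and Clec4a1 (3.16 ± 0.23) among genes whose groups did not overlap. Ceacam15, Dscam, Cybb, Ccr6, Gpnmb and Mest followed, at 3.14 to 2.75. The genes most below CD11b- cells were Clec9a (≤ -4.96 ± 0.13), Xcr1 (≤ -4.06 ± 0.25), Rab7b (-3.97 ± 0.18) and Stfa2 (≤ -3.50 ± 0.18). Lyz2, Dnase1l3, Cd207, Bst1, Ifi205 and Cd36 followed, at -3.42 to -2.51. Of these 20, 12 rest on a level near background, their order uncertain. Adgre1 encodes the macrophage marker F4/80 and Lyz2 a lysozyme, and the monocyte and macrophage markers list was not called (camera adjusted p = 0.276). Cd8a (≥ 1.03 ± 0.13), Dhrs3 (0.90 ± 0.13) and Trem1 (≥ 1.00 ± 0.12, 117 against 58.3, both near background) were higher. Itgae (-1.40 ± 0.19), Irf8 (-0.61 ± 0.11) and Itgb7 (-0.77 ± 0.17) were lower. Irf4 (0.36 ± 0.20), Flt3 (-0.09 ± 0.11) and Csf2rb (-0.23 ± 0.13) were not called. Batf3 (-0.07 ± 0.22, adjusted p = 0.918, 0.712 to 0.982 over alternatives) changed sign without replicate 3 of CD11b+ cells without RA (0.0525). Aldh1a2 (≤ -0.51 ± 0.16, adjusted p = 0.0370, 0.0339 to 0.205 over alternatives) was not called with every probe set tested (0.0554), with only the compared groups fitted (0.0548) and without replicate 2 or 3 of CD11b- cells without RA or replicate 1 or 3 of CD11b+ cells without RA (0.0534 to 0.205). Rara (-0.50 ± 0.15, adjusted p = 0.0341, 0.000814 to 0.160 over alternatives) was not called with every probe set tested (0.0503) and without replicate 2 or 3 of CD11b- cells without RA or replicate 1 or 2 of CD11b+ cells without RA (0.0728 to 0.160). Rarb (0.28 ± 0.11, adjusted p = 0.121, 0.0111 to 0.399 over alternatives) was called with array weights (0.0111). Ccr9 (-0.56 ± 0.20, adjusted p = 0.0697, 0.00621 to 0.382 over alternatives) was called with the replicate block (0.0323), with the cultured-array block (0.0363), with array weights (0.00621) and without replicate 3 of CD11b+ cells without RA (0.00856). Cd101 (0.02 ± 0.13, adjusted p = 0.965, 0.654 to 0.997 over alternatives) changed sign with quantile normalization (-0.0134) and without replicate 1 of CD11b- cells without RA or replicate 2 of CD11b+ cells without RA (-0.0827 to -0.0341). Zbtb46 (0.03 ± 0.13, adjusted p = 0.946, 0.600 to 0.973 over alternatives) changed sign without replicate 3 of CD11b- cells without RA or replicate 1 or 2 of CD11b+ cells without RA (-0.0466 to -0.0179).

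In this comparison 1601 of 12387 genes were called at an adjusted p under 0.05 by limma, 775 higher and 826 lower, and 293 differed at least 2-fold. Over all genes, the arrays of the subsets did not overlap in 3902 (31.5%), where chance gives 10%. With array weights the count was 2628, in place of 1601.

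The same comparison with RA in both cultures addressed how far apart the subsets stood when RA was present. In CD11b+ cells with RA, maturation genes were higher and cell cycle genes lower than in CD11b- cells. Of 23 costimulation and maturation list members, 21 were higher and 0 lower (21 and 0 adjusted over the list alone), with a median log2 of 1.67. The costimulation and maturation list gave camera adjusted p = 2.46e-17 (1.28e-20 to 1.54e-13 over alternatives), adjusted p = 0.257 with an estimated correlation. Cd40 (1.81 ± 0.12), Relb (2.21 ± 0.15) and Tnfsf4 (≥ 3.04 ± 0.22) were higher. Of 32 cell cycle list members, 0 were higher and 32 lower (0 and 32 adjusted over the list alone), with a median log2 of -1.03. The cell cycle list gave camera adjusted p = 8.75e-12 (4.20e-13 to 6.00e-09 over alternatives), adjusted p = 0.365 with an estimated correlation. The replication genes Cdc45 (-1.43 ± 0.15), Rrm2 (-1.56 ± 0.19) and Mcm5 (-1.29 ± 0.16) were lower.

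The subset markers differed with RA too. Of 21 cDC1 markers list members, 0 were higher and 17 lower (1 and 17 adjusted over the list alone), with a median log2 of -2.58. The cDC1 markers list gave camera adjusted p = 3.93e-12 (4.08e-14 to 1.07e-07 over alternatives), adjusted p = 0.236 with an estimated correlation. Clec9a was at least 77.7-fold lower (≤ -6.28 ± 0.13, adjusted p = 5.89e-17) and Tlr3 at least 46.3-fold (≤ -5.53 ± 0.15). Of 20 cDC2 markers list members, 14 were higher and 2 lower (14 and 3 adjusted over the list alone), with a median log2 of 1.33. The cDC2 markers list gave camera adjusted p = 1.99e-08 (5.63e-09 to 3.25e-06 over alternatives), adjusted p = 0.232 with an estimated correlation. Irf4 was 8.91-fold higher (3.16 ± 0.20) and Sirpa 13.7-fold (3.77 ± 0.15). Of 26 dendritic cell transcription factors list members, 11 were higher and 6 lower (13 and 6 adjusted over the list alone), with a median log2 of 0.27. The list gave camera adjusted p = 0.0226 (0.00949 to 0.140 over alternatives), adjusted p = 0.510 with an estimated correlation. Zeb2 (≥ 2.05 ± 0.13) and Prdm1 (2.10 ± 0.16) were higher. For dendritic cell transcription factors, the call ended without the genes below the median level (0.140) and with the cultured-array block (0.0619). Of 26 cytokines and chemokines list members, 14 were higher and 3 lower (14 and 5 adjusted over the list alone), with a median log2 of 0.63. The cytokines and chemokines list gave camera adjusted p = 0.000242 (2.90e-05 to 0.00191 over alternatives), adjusted p = 0.365 with an estimated correlation. Cxcl10 (2.24 ± 0.16) and Ccl5 (2.12 ± 0.16) were higher. Of 18 type I interferon response list members, 8 were higher and 3 lower (13 and 3 adjusted over the list alone), with a median log2 of 0.46. The type I interferon response list gave camera adjusted p = 0.00288 (0.00116 to 0.554 over alternatives), adjusted p = 0.369 with an estimated correlation. Usp18 (1.66 ± 0.12) was higher. For type I interferon response, the call ended without the genes below the median level (0.554). Of 16 monocyte and macrophage markers list members, 10 were higher and 2 lower (10 and 2 adjusted over the list alone), with a median log2 of 0.62. The list gave camera adjusted p = 0.00217 (0.000343 to 0.272 over alternatives), adjusted p = 0.365 with an estimated correlation. Mertk (≥ 2.84 ± 0.13) and C1qb (≥ 3.49 ± 0.26) were higher. For monocyte and macrophage markers, the call ended without the genes below the median level (0.272). Of 18 cholesterol and fatty acid synthesis list members, 0 were higher and 15 lower (0 and 16 adjusted over the list alone), with a median log2 of -0.65. The list gave camera adjusted p = 5.32e-05 (1.53e-05 to 0.000353 over alternatives), adjusted p = 0.365 with an estimated correlation. Lss (-1.37 ± 0.11) and Dhcr7 (-1.26 ± 0.13) were lower.

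The genes most above CD11b- cells with RA were Klk1b11 (≥ 5.98 ± 0.14), Clec4n (≥ 4.29 ± 0.24), Adgrg6 (4.02 ± 0.17) and Klrb1f (≥ 3.97 ± 0.22) among genes whose groups did not overlap. Tmem176b, Tmem176a, Gpnmb, Ptk6, Sirpa and Wfdc17 followed, at 3.97 to 3.75. The genes most below CD11b- cells with RA were Clec9a (≤ -6.28 ± 0.13), Xcr1 (≤ -5.85 ± 0.25), Tlr3 (≤ -5.53 ± 0.15) and Clec4b2 (≤ -5.21 ± 0.22). Gpr33, Rasgrp3, Cd34, Btla, Gpr141b and Ctla2b followed, at -4.85 to -3.68. Of these 20, 13 rest on a level near background, their order uncertain. Itgam, the sorting marker, differed by 1.66 ± 0.17. Aldh1a2 (1.41 ± 0.16), Dhrs3 (1.49 ± 0.13), Trem1 (≥ 2.45 ± 0.12), Cd101 (≥ 1.40 ± 0.13) and Csf2rb (0.51 ± 0.13) were higher. Itgae (-1.51 ± 0.19), Irf8 (-1.01 ± 0.11), Rara (-0.60 ± 0.15), Rarb (-0.75 ± 0.11) and Ccr9 (≤ -1.19 ± 0.20) were lower. Itgb7 (-0.76 ± 0.17) and Flt3 (-0.75 ± 0.11) were lower. Cd8a (0.23 ± 0.13) was not called. Batf3 (0.50 ± 0.22, adjusted p = 0.0732, 0.00338 to 0.438 over alternatives) was called with quantile normalization (0.0393), with arrays centred on their median (0.0262), with array weights (0.00546) and without replicate 3 of CD11b- cells with RA or replicate 2 of CD11b+ cells with RA (0.00338 to 0.0469). Zbtb46 (0.42 ± 0.13, adjusted p = 0.0133, 0.00200 to 0.0849 over alternatives) was not called without replicate 1 of CD11b- cells with RA or replicate 3 of CD11b+ cells with RA (0.0594 to 0.0849).

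In this comparison 5129 of 12387 genes were called at an adjusted p under 0.05 by limma, 1924 higher and 3205 lower, and 1116 differed at least 2-fold. Over all genes, the arrays of the subsets did not overlap in 5977 (48.3%), where chance gives 10%. With each array centred on its median the calls split into 2419 higher and 2497 lower genes, in place of 1924 and 3205.

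Whether the RA effect differed between the subsets was tested as the effect in CD11b+ cells minus that in CD11b- cells, so higher means a higher effect in CD11b+ cells. The effect on maturation genes was higher and that on cell cycle genes lower. The maturation list fell in CD11b- cells (median -1.78). It was not called in CD11b+ cells (median -0.13, camera adjusted p = 0.448), so higher is no rise there. Of 23 costimulation and maturation list members, 20 were higher and 2 lower (20 and 2 adjusted over the list alone), with a median log2 of 1.66. The list gave camera adjusted p = 1.74e-16 (3.62e-20 to 7.61e-12 over alternatives), adjusted p = 0.270 with an estimated correlation. Cd40 (2.21 ± 0.17), Tnfrsf4 (2.34 ± 0.21) and Cd274 (1.61 ± 0.18) were higher. Of 32 cell cycle list members, 0 were higher and 29 lower (0 and 29 adjusted over the list alone), with a median log2 of -1.26. The cell cycle list gave camera adjusted p = 9.05e-15 (2.01e-16 to 1.47e-11 over alternatives), adjusted p = 0.345 with an estimated correlation. Mcm6 (-1.78 ± 0.23) and Mcm7 (-1.43 ± 0.21) were lower. Of 21 cDC1 markers list members, 2 were higher and 11 lower (2 and 12 adjusted over the list alone), with a median log2 of -0.70. The cDC1 markers list gave camera adjusted p = 0.00227 (0.000502 to 0.0842 over alternatives), adjusted p = 0.416 with an estimated correlation. Tlr3 (-3.60 ± 0.22), Btla (-2.91 ± 0.23) and Clec9a (-1.32 ± 0.18) were lower. For cDC1 markers, the call ended without the genes below the median level (0.0842). Of 20 cDC2 markers list members, 8 were higher and 3 lower (8 and 3 adjusted over the list alone), with a median log2 of 0.26. The cDC2 markers list gave camera adjusted p = 0.00310 (0.000459 to 0.00973 over alternatives), adjusted p = 0.365 with an estimated correlation. Mgl2 (3.24 ± 0.32), Irf4 (2.79 ± 0.29) and Clec10a (3.11 ± 0.32) were higher.

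The RA effect also differed for cytokine, lipid and macrophage lists. Of 26 cytokines and chemokines list members, 10 were higher and 2 lower (11 and 2 adjusted over the list alone), with a median log2 of 0.40. The list gave camera adjusted p = 0.00299 (0.000692 to 0.0194 over alternatives), adjusted p = 0.416 with an estimated correlation. Ccl5 (2.34 ± 0.22) and Il12b (2.68 ± 0.38) were higher. Of 13 LXR and PPAR responsive lipid genes list members, 5 were higher and 2 lower (5 and 3 adjusted over the list alone), with a median log2 of 0.23. The list gave camera adjusted p = 0.00642 (0.00383 to 0.408 over alternatives), adjusted p = 0.257 with an estimated correlation. Fabp5 (2.99 ± 0.27) and Apoe (1.57 ± 0.19) were higher. For LXR and PPAR responsive lipid genes, the call ended without the genes below the median level (0.408). Of 16 monocyte and macrophage markers list members, 6 were higher and 3 lower (6 and 3 adjusted over the list alone), with a median log2 of 0.27. The list gave camera adjusted p = 0.0177 (0.00216 to 0.286 over alternatives), adjusted p = 0.408 with an estimated correlation. Mertk (2.91 ± 0.19) was higher. For monocyte and macrophage markers, the call ended with quantile normalization (0.0530) and without the genes below the median level (0.286). Of 18 cholesterol and fatty acid synthesis list members, 0 were higher and 5 lower (0 and 5 adjusted over the list alone), with a median log2 of -0.38. The list gave camera adjusted p = 0.0354 (0.0145 to 0.0766 over alternatives), adjusted p = 0.635 with an estimated correlation. Dhcr7 (-1.07 ± 0.18) was lower. For cholesterol and fatty acid synthesis, the call ended without the genes below the median level (0.0552) and without replicate 3 of CD11b- cells without RA or replicate 3 of CD11b- cells with RA or replicate 3 of CD11b+ cells with RA (0.0538 to 0.0766). Of 26 dendritic cell transcription factors list members, 6 were higher and 5 lower (7 and 6 adjusted over the list alone), with a median log2 of 0.19. The list gave camera adjusted p = 0.0395 (0.0222 to 0.0950 over alternatives), adjusted p = 0.570 with an estimated correlation. Prdm1 (2.71 ± 0.23) and Relb (1.92 ± 0.22) were higher. For dendritic cell transcription factors, the call ended with quantile normalization (0.0761), with arrays centred on their median (0.0536), without the genes below the median level (0.0950), with the replicate block (0.0557), with the cultured-array block (0.0922) and without replicate 2 of CD11b- cells without RA or replicate 2 of CD11b+ cells without RA or replicate 1 of CD11b- cells with RA or replicate 3 of CD11b+ cells with RA (0.0501 to 0.0780).

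The largest positive differences of the RA effect were Klk1b11 (3.76 ± 0.20), Adgrg6 (3.74 ± 0.24), Lpl (3.68 ± 0.16), Gclc (3.43 ± 0.18) and H2-Eb2 (3.39 ± 0.24). Adgrg6 (-4.61 in CD11b- and -0.86 in CD11b+ cells) and H2-Eb2 (-4.15 and -0.76) were lower with RA in both. The largest negative differences of the RA effect were Pilra (-4.15 ± 0.23), Ifitm6 (-3.76 ± 0.25), Tlr3 (-3.60 ± 0.22), Cd34 (-3.56 ± 0.22) and Ppef1 (-3.23 ± 0.19). Of these 10, 7 lie near background in at least 1 group (Klk1b11, Lpl, Pilra, Ifitm6, Tlr3, Cd34 and Ppef1). So do Clec9a, Mertk, Aldh1a2 and others, so size and order are uncertain for all. Sirpa (1.56 ± 0.21), Aldh1a2 (1.93 ± 0.22), Trem1 (1.44 ± 0.17), Cd101 (1.37 ± 0.18) and Csf2rb (0.75 ± 0.19) were higher. Cd8a (-0.80 ± 0.19), Rarb (-1.03 ± 0.16), Flt3 (-0.67 ± 0.15) and Xcr1 (-1.79 ± 0.35) were lower. Itgae (-0.11 ± 0.26, adjusted p = 0.828, 0.440 to 0.999 over alternatives) changed sign with arrays centred on their median (0.00221) and without replicate 3 of CD11b+ cells without RA (0.162). Itgam (-0.41 ± 0.24, adjusted p = 0.238, 0.0478 to 0.789 over alternatives) was called without replicate 1 of CD11b- cells without RA (0.0478). Irf8 (-0.40 ± 0.16, adjusted p = 0.0768, 0.0245 to 0.221 over alternatives) was called with array weights (0.0433) and without replicate 3 of CD11b+ cells with RA (0.0245). Batf3 (0.57 ± 0.30, adjusted p = 0.200, 0.0194 to 0.501 over alternatives) was called with array weights (0.0194) and without replicate 3 of CD11b- cells with RA (0.0217). Rara (-0.10 ± 0.21, adjusted p = 0.805, 0.415 to 0.978 over alternatives) changed sign with arrays centred on their median (0.0118) and without replicate 1 of CD11b+ cells with RA (0.0385). Dhrs3 (0.59 ± 0.18, adjusted p = 0.0208, 0.00955 to 0.0731 over alternatives) was not called without replicate 2 of CD11b- cells without RA or replicate 3 of CD11b+ cells without RA or replicate 2 of CD11b- cells with RA or replicate 3 of CD11b+ cells with RA (0.0503 to 0.0731). Ccr9 (-0.63 ± 0.28, adjusted p = 0.108, 0.0263 to 0.527 over alternatives) was called without replicate 2 of CD11b+ cells without RA or replicate 2 of CD11b- cells with RA (0.0263 to 0.0479). Itgb7 (0.02 ± 0.24, adjusted p = 0.969, 0.676 to 0.973 over alternatives) changed sign without replicate 3 of CD11b- cells without RA or replicate 1 or 2 of CD11b+ cells without RA or replicate 1 or 2 of CD11b- cells with RA or replicate 3 of CD11b+ cells with RA (-0.105 to -0.0314). Zbtb46 (0.39 ± 0.18, adjusted p = 0.136, 0.0417 to 0.362 over alternatives) was called with arrays centred on their median (0.0485), with array weights (0.0440) and without replicate 2 of CD11b+ cells with RA (0.0417).

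In this comparison 3049 of 12387 genes were called at an adjusted p under 0.05 by limma, 1196 higher and 1853 lower, and 991 differed at least 2-fold. Of the called genes, 1835 were called with RA in CD11b- cells alone, 291 in CD11b+ cells alone and 70 in neither. Called in both were 706 in the same direction, 610 of them more in CD11b- and 96 more in CD11b+ cells, and 147 in opposite directions. With each array centred on its median the calls split into 1551 higher and 1308 lower genes, in place of 1196 and 1853.

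**Figure D3:**
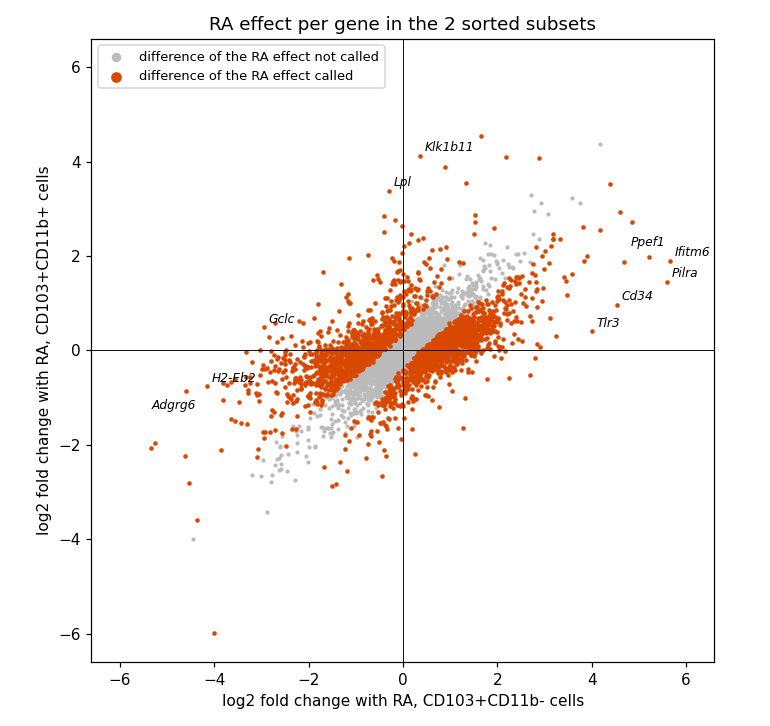
RA effect per gene in the sorted subsets. The axes give the log2 fold change with RA in CD11b- cells (x) and CD11b+ cells (y), each dot is a gene, coloured where the difference of the RA effect was called, and the 10 genes with the largest called differences are named. The effects correlate at r = 0.624 across genes.

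The cultured cells, as the mean of their 4 groups, were compared with the pre-uDC, and this difference cannot be told apart from the labelled age of the mice, the culture or any batch. Cultured cells had lower levels of plasmacytoid DC markers and cell cycle genes and higher levels of maturation genes. Of 18 plasmacytoid dendritic cell markers list members, 0 were higher and 17 lower (1 and 17 adjusted over the list alone), with a median log2 of -2.31. The list gave camera adjusted p = 4.64e-13 (3.85e-14 to 0.000152 over alternatives), adjusted p = 0.00608 with an estimated correlation. Mctp2 was at least 30.0-fold lower (≤ -4.91 ± 0.11). Ly6d (≤ -4.90 ± 0.13), Siglech (≤ -4.80 ± 0.15) and Tlr7 (≤ -3.26 ± 0.10) were lower. Of 23 costimulation and maturation list members, 22 were higher and 0 lower (22 and 0 adjusted over the list alone), with a median log2 of 3.06. The list gave camera adjusted p = 7.94e-15 (1.84e-16 to 9.13e-11 over alternatives), adjusted p = 0.309 with an estimated correlation. The chemokine Ccl22 was at least 64.8-fold higher (≥ 6.02 ± 0.11) and Ccl17 at least 55.1-fold (≥ 5.78 ± 0.13). Of 32 cell cycle list members, 0 were higher and 30 lower (0 and 30 adjusted over the list alone), with a median log2 of -1.24. The cell cycle list gave camera adjusted p = 6.79e-13 (1.07e-13 to 3.88e-11 over alternatives), adjusted p = 0.365 with an estimated correlation. Foxm1 (-2.30 ± 0.10) and Mki67 (-1.73 ± 0.12) were lower.

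Genes of progenitors, neutrophils and antigen presentation differed as well. Of 15 myeloid progenitor genes list members, 0 were higher and 12 lower (0 and 12 adjusted over the list alone), with a median log2 of -0.83. The list gave camera adjusted p = 1.59e-05 (2.61e-06 to 0.886 over alternatives), adjusted p = 0.133 with an estimated correlation. Myb (-3.07 ± 0.09) and Mpo (-3.26 ± 0.19) were lower. For myeloid progenitor genes, the call ended without the genes below the median level (0.886). Of 10 neutrophil markers list members, 1 was higher and 9 lower (1 and 9 adjusted over the list alone), with a median log2 of -1.59. The list gave camera adjusted p = 6.87e-05 (1.38e-06 to 0.000622 over alternatives), adjusted p = 0.365 with an estimated correlation. Ngp (≤ -4.57 ± 0.20) and S100a8 (≤ -2.58 ± 0.14) were lower. Of 10 MHC class II presentation list members, 9 were higher and 0 lower (9 and 0 adjusted over the list alone), with a median log2 of 0.62. The list gave camera adjusted p = 0.00787 (0.00293 to 0.0552 over alternatives), adjusted p = 0.513 with an estimated correlation. H2-Ob (2.00 ± 0.14) and Ciita (1.25 ± 0.13) were higher. For MHC class II presentation, the call ended without the genes below the median level (0.0552). Of 13 intestinal dendritic cell candidate markers list members, 9 were higher and 0 lower (9 and 0 adjusted over the list alone), with a median log2 of 0.63. The list gave camera adjusted p = 0.00238 (0.00134 to 0.0378 over alternatives), adjusted p = 0.236 with an estimated correlation. Plet1 (≥ 6.02 ± 0.10), Cdh1 (3.47 ± 0.13) and Ido1 (≥ 2.76 ± 0.12) were higher. Of 15 retinoic acid receptors and responsive genes list members, 8 were higher and 1 lower (9 and 1 adjusted over the list alone), with a median log2 of 0.46. The list gave camera adjusted p = 0.0401 (0.0286 to 0.140 over alternatives), adjusted p = 0.365 with an estimated correlation. Asb2 (3.48 ± 0.12) and Ncoa7 (2.11 ± 0.12) were higher. For retinoic acid receptors and responsive genes, the call ended without the genes below the median level (0.140). Of 26 cytokines and chemokines list members, 19 were higher and 3 lower (19 and 4 adjusted over the list alone), with a median log2 of 1.28. The list gave camera adjusted p = 0.00102 (0.000222 to 0.00500 over alternatives), adjusted p = 0.373 with an estimated correlation. Ccl5 (3.84 ± 0.13) and Cxcl16 (3.82 ± 0.13) were higher.

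The genes most above pre-uDC were Serpinb6b (≥ 6.18 ± 0.13), Socs2 (≥ 6.06 ± 0.12), Plet1 (≥ 6.02 ± 0.10) and Ccl22 (≥ 6.02 ± 0.11) among genes whose groups did not overlap. Serpinb9, Ccl17, Sema6d and Il1r2 followed, at 5.79 to 5.29. The genes most below pre-uDC were Serpinb10 (≤ -5.30 ± 0.09), Gria3 (≤ -5.26 ± 0.12), Ly6a2 (≤ -5.03 ± 0.14) and Mctp2 (≤ -4.91 ± 0.11). Ly6d, Siglech, Ccr2 and Ngp followed, at -4.90 to -4.57. Of these 16, 16 rest on a level near background, their order uncertain. The difference in Itgae (≥ 4.82 ± 0.15) is no finding, since Itgae encodes CD103 and the cultured cells were sorted for it. Irf4 (2.63 ± 0.16), Batf3 (0.79 ± 0.17), Aldh1a2 (≥ 2.82 ± 0.13), Rarb (≥ 0.66 ± 0.09) and Trem1 (≥ 0.78 ± 0.10) were higher. Csf2rb (2.48 ± 0.11), Xcr1 (1.06 ± 0.20) and Zbtb46 (0.94 ± 0.10) were higher. Irf8 (-0.36 ± 0.09), Cd8a (-0.78 ± 0.11), Sirpa (-1.57 ± 0.12), Dhrs3 (-0.98 ± 0.10) and Ccr9 (≤ -2.54 ± 0.15) were lower. Itgb7 (-1.02 ± 0.13) and Clec9a (-2.55 ± 0.10) were lower. Itgam (0.08 ± 0.13, adjusted p = 0.633, 0.440 to 0.967 over alternatives) changed sign with quantile normalization (-0.0544). Rara (0.21 ± 0.12, adjusted p = 0.139, 0.0265 to 0.703 over alternatives) was called with the replicate block (0.0428) and without replicate 3 of pre-uDC (0.0265). Cd101 (0.18 ± 0.10, adjusted p = 0.137, 0.0433 to 0.397 over alternatives) was called without replicate 3 of CD11b+ cells with RA (0.0433). Flt3 (0.15 ± 0.08, adjusted p = 0.133, 0.0437 to 0.933 over alternatives) was called without replicate 2 of CD11b+ cells with RA (0.0437).

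In this comparison 7438 of 12387 genes were called at an adjusted p under 0.05 by limma, 4318 higher and 3120 lower, and 1852 differed at least 2-fold. Over all genes, the precursor and cultured arrays did not overlap in 3482 (28.1%), where chance gives 0.44%. The calls split into 3842 higher and 3941 lower genes with quantile normalization and into 3819 and 3722 with each array centred on its median, so the excess of higher over lower genes rests on the scaling of the arrays.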

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

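The tests of CD11b+ cells in the CD11b- sort and of unchanged precursors were chosen after the results they measure had been seen, and the other tests in this part were not.

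The RA effect differed between the subsets for 3049 genes by limma's test of the difference itself, and 10 of them stood out by the size of that difference. It was 3.76 for Klk1b11, 3.74 for Adgrg6, 3.68 for Lpl, 3.43 for Gclc, 3.39 for H2-Eb2, -4.15 for Pilra, -3.76 for Ifitm6, -3.60 for Tlr3, -3.56 for Cd34 and -3.23 for Ppef1, as log2 of the effect in CD11b+ over that in CD11b- cells, and all but Adgrg6, Gclc and H2-Eb2 rest on a level near background in at least 1 group, so their size is uncertain. Of 100 random splits of the 12 cultured arrays, only the real one gave as many genes (next 2345). The splits mix RA and subset effects and ignore replicate numbers, so they do not test this difference.

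Itgam rose with RA in the CD11b- cells from an intensity of 115 to 625, although the sort removes cells with surface CD11b. A share of 27.5% of CD11b+ cells, at 1968, could bring that level, but of 72 genes at least 2-fold higher in CD11b+ cells without RA and at 500 or more in CD11b+ cells with RA, 15, or 20.8%, lay below 50% of the level that this share would bring, between the bounds of 5% set for such cells as the cause and 25% set against it, and 27 lay below without that margin (37.5%). Abundant transcripts far below it were Klk1b11 (49.4 against 858), Sirpa (150 against 562), Cybb (214 against 670) and Tnip3 (254 against 693), which argues against cells like the sorted CD11b+ cells as the whole source, while an earlier test on 7 cDC2 markers decided nothing (median log2 of -1.17 from the prediction, quartiles -2.07 to 0.07). Cells that carry CD11b but lack these transcripts cannot be told apart from a rise of Itgam in the CD11b- cells themselves, and Itgam also rose 4.09-fold with RA in CD11b+ cells.

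Cd3g fell with RA at least 16.1-fold in CD11b- and at least 63.3-fold in CD11b+ cells, from a level of 2968 in CD11b+ cells without RA. If T cells in the cultures without RA were the source, which the sort on CD103 and CD11b would have to pass, other T cell transcripts would fall as well. Over the 7 measured of 16 T cell genes listed before the test, the median RA effect in CD11b+ cells was -0.27, above the bound of -0.5 set beforehand, but its quartiles, -1.05 and 0.01, span that bound. Cd28 (≤ -2.12, from 218) and Cd6 (-1.79, from 456) fell with Cd3g. So did, outside the list, Icos (≤ -4.45 in CD11b- and -4.00 in CD11b+ cells, from 2168 and 2162) and Grap2 (-2.66 in CD11b+ cells, with 929 in pre-uDC). In CD11b+ cells Thy1 rose (0.55), while Il7r (2863 to 2382) and, outside the list, Cd3e (125 to 150) stayed uncalled. Cd3e fell in CD11b- cells (150 to 108). Lat, Bcl11b and Ubash3a lay near 100, too dim to decide. T cells and a change in the DC cannot be told apart without T cell arrays.

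In CD11b- cells with RA, the cell cycle genes were higher and the maturation genes lower, both changes toward the levels of pre-uDC. Precursors that had not changed in culture would need a share of 81.0% to bring the cell cycle levels, and the 17 called plasmacytoid-list genes that mark pre-uDC would then rise by a median of 2.14. Their median RA effect was -0.22 (quartiles -0.48 to 0.06), and 17 of 17 lay below the prediction, which argues against unchanged precursors as the cause. No setting run for lists ended either list's call (7.86e-15 to 1.31e-10 and 4.32e-14 to 5.02e-09 over their alternatives, the estimated correlation apart). A mixture with other dividing cells was not tested and stays open, as does an effect of RA on the cells themselves.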

How the results depend on the processing

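The replicate block among the cultured arrays alone and the correlation of the RA effects between differently numbered arrays were chosen after seeing the data, and all other alternatives were planned. Of the 587 called gene results under the naming rule, 548 kept direction and call under every alternative that could be run, and no called gene result reversed. Counts of called genes stayed within 1.5 times of those reported, except as follows. Leaving out the genes below the median level, which tests fewer genes by construction, gave 3496 and 1503 genes for the RA effect in CD11b- and CD11b+ cells. It gave 862 and 3164 for the subset comparison without and with RA, 1811 for the difference of the RA effect, 4350 for the precursor comparison and 1134 for the overlap of the RA effects. Array weights gave 2628 genes for the subset comparison without RA, and the cause was not tested. Leaving out single arrays gave 5129 to 5562, 2106 to 2696, 1183 to 1519, 4503 to 4823, 2457 to 3204 and 6758 to 7471 genes in the same order, and an overlap of 1554 to 1997. With the replicate block, the paired fit, the counts were 6452, 3170, 1915, 5591, 3621 and 7838, and the overlap 2283. With the block among the cultured arrays alone they were 7015, 3776, 2334, 6204 and 4279, and the overlap 2678. The replicate block changed the calls of Ccr9 between subsets without RA, of Rara in the precursor comparison and of the dendritic cell transcription factors list for the difference of the RA effect, and no other call of a named gene or list. For CD11b+ cells with and without RA, 1 pair (r = 0.041) lay below differently numbered arrays (to 0.063).

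Gene results that turned direction were uncalled in the reported fit, and the cause was not tested. With quantile normalization these were Irf4 in the RA effect in CD11b+ cells (0.0212), Cd101 between subsets without RA (-0.0134) and Itgam in the precursor comparison (-0.0544). Centred arrays turned Itgae (0.00221) and Rara (0.0118) in the difference of the RA effect, and array weights turned Irf4 in CD11b+ cells (0.0153). Leaving out single arrays gave -0.104 to 0.0955 for Irf4, -0.0683 to 0.230 for Batf3 and -0.0511 to 0.203 for Zbtb46 in the RA effect in CD11b+ cells, and -0.137 to 0.0318 for Cd8a in CD11b- cells. Between subsets without RA it gave -0.0827 to 0.0837 for Cd101, -0.222 to 0.0525 for Batf3 and -0.0466 to 0.159 for Zbtb46. For the difference of the RA effect it gave -0.301 to 0.162 for Itgae, -0.213 to 0.0385 for Rara and -0.105 to 0.153 for Itgb7. Of 51 list calls, 1 was kept with an estimated correlation and 29 were the same under every other setting run for lists. The neutrophil markers list in the precursor comparison was the same under the others but, like the T and NK cell markers list between subsets without RA, kept too few members to be run without the genes below the median level. Without those genes 18 ended and 1, the type I interferon response list between subsets without RA, turned direction (adjusted p = 0.914). Signal over background limits genes near an intensity of 120 or below, where changes shrink.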

Other observations

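The tests in this part were chosen before their results were seen, except where said otherwise. Cultured cells differed from pre-uDC in metabolic genes. Of 17 glycolysis and hypoxia list members, 17 were higher and 0 lower (17 and 0 adjusted over the list alone), with a median log2 of 2.17. The list gave camera adjusted p = 3.19e-09 (9.15e-10 to 1.25e-06 over alternatives), adjusted p = 0.257 with an estimated correlation. Aldoa (2.35 ± 0.08), Pgk1 (2.42 ± 0.10) and Slc16a3 (2.63 ± 0.11) were higher. Of 18 cholesterol and fatty acid synthesis list members, 18 were higher and 0 lower (18 and 0 adjusted over the list alone), with a median log2 of 1.67. The cholesterol and fatty acid synthesis list gave camera adjusted p = 2.07e-09 (4.02e-11 to 9.46e-07 over alternatives), adjusted p = 0.257 with an estimated correlation. The desaturase Scd1 was at least 37.0-fold higher (≥ 5.21 ± 0.12). Of 13 LXR and PPAR responsive lipid genes list members, 9 were higher and 2 lower (9 and 2 adjusted over the list alone), with a median log2 of 0.52. The list gave camera adjusted p = 0.0380 (0.0274 to 0.357 over alternatives), adjusted p = 0.365 with an estimated correlation. Abcg1 (2.04 ± 0.10) and Fabp5 (2.59 ± 0.15) were higher. For LXR and PPAR responsive lipid genes, the call ended without the genes below the median level (0.357). Of 14 immediate early and heat shock genes list members, 10 were higher and 0 lower (11 and 0 adjusted over the list alone), with a median log2 of 0.80. The list gave camera adjusted p = 0.00219 (0.00101 to 0.0136 over alternatives), adjusted p = 0.377 with an estimated correlation. Egr2 (≥ 3.56 ± 0.14) and Atf3 (3.43 ± 0.13) were higher.

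Lists of the TGF-beta pathway and of some other cell types were not called in any comparison. With RA in CD11b+ cells, Lrrc32, which anchors latent TGF-beta on the cell surface, rose at least 6.62-fold (≥ 2.73 ± 0.23) and Smad3 fell (-0.98 ± 0.11). Of 15 TGF-beta pathway list members, 5 were higher and 3 lower (6 and 3 adjusted over the list alone), with a median log2 of 0.01. The list gave camera adjusted p = 0.422, not called. With RA in CD11b- cells, the carbonic anhydrase Car2 was 10.1-fold lower (-3.33 ± 0.21). Of 4 erythroid markers list members, 0 were higher and 1 lower (0 and 1 adjusted over the list alone), with a median log2 of -0.11. The list gave camera adjusted p = 0.257, not called. In cultured cells against pre-uDC, Cd79b (≤ -2.88 ± 0.10) and Cd22 (≤ -3.41 ± 0.14) were lower. Of 6 B cell markers list members, 1 was higher and 3 lower (1 and 3 adjusted over the list alone), with a median log2 of -0.23. The B cell markers list gave camera adjusted p = 0.198, not called. Of 2 mast cell, basophil and eosinophil markers list members, 0 were higher and 2 lower (0 and 2 adjusted over the list alone), with a median log2 of -0.31. The list gave camera adjusted p = 0.386, not called.

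A hypothesis was that cells cultured with RA stood less far along the change from precursor to cultured cell. It was tested between contrasts that share no array. The RA effect in CD11b- cells correlated at r = -0.60 across 12387 genes with the difference between CD11b+ cells without RA and pre-uDC. The RA effect in CD11b+ cells correlated at r = -0.34 with the difference between CD11b- cells without RA and pre-uDC. Both lie beyond the -0.3 set beforehand. But the cultures without RA, alike in both subsets (mean r = 0.971), enter the contrasts with opposite signs. This by itself pushes r below 0, so the bound cannot decide. Arrays with the same number also deviate together between these cultures (0.438 to 0.677). 2 further tests were chosen after the results were seen. With same-numbered arrays kept apart, r was -0.616 to -0.538 in CD11b- cells and -0.411 to -0.139 in CD11b+ cells, above the bound for part of the latter. The opposite signs remain there. Of the 13 lists called between cultured cells and pre-uDC, 2 moved toward pre-uDC with RA in CD11b- cells (cell cycle, costimulation and maturation) and 1 in CD11b+ cells (neutrophil markers, median 0.09) by both quartiles, and 1 and 3 moved further from it. The glycolysis and hypoxia list moved further in both subsets (median RA effect 1.13 and 0.64), the cytokines and chemokines list in CD11b+ cells (0.32) and there also the MHC class II presentation list (0.03), without a called member. The plasmacytoid dendritic cell markers list, lower in cultured cells, did not return with RA (-0.25 and -0.14). This argues against 1 position along the change shared by all gene groups, and a change limited to groups such as cell cycle and maturation genes stays open. Genes are not independent replicates, and the hypothesis was formed on these data. The labels give pre-uDC and cultures different ages, and age was not tested.

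For each comparison of 3 against 3 arrays, 10 splits exist, too few for a share under 0.05. The real counts were 5957 and 2730 for the RA effect in CD11b- and CD11b+ cells and 1601 and 5129 for the subset comparison without and with RA. The highest other split gave 0 in each, also among the splits that part all 3 pairs, and 1 split, the real one, gave as many genes as observed. For the precursor comparison, 1 of 100 splits, the real one, gave 7438 genes or more, and the highest of the others gave 1157. Any other split, here and for 3 against 3 arrays, mixes the groups and widens the spread, so it cannot exclude a random grouping.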
